A study of Homo sapiens with 12 samples.

How the data were processed

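Gene expression was measured by RNA sequencing of LM-Seq libraries made from total RNA of sorted cells, per the labels' protocols. The submitters' processing notes list CASAVA 1.8.2, Bowtie 0.12.9, RSEM 1.2.3 and the genome build hg19. The role and order of these tools, and the annotation, are not given in the sources used here. RSEM estimates how reads that match several genes are divided, so values of near-identical genes are uncertain, and whether strand was used in counting is not given in the sources used here.

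The authors deposited 1 table of counts and 1 table of TPM for 23686 genes, named by gene symbol, in 12 libraries. The deposited counts were read as RSEM expected counts that the authors had rounded to whole numbers, an inference from the values: they are whole, and 79 day 5 values and 25 day 4 values are 0 in the counts but above 0 in the TPM table. The deposited TPM values are scaled within each library to gene length and a common total, so they carry no depth. Columns belonging to other samples numbered 0.

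Groups followed the labels: fraction, line, dox and dose. Whether libraries came from separate differentiation experiments is not stated, so p-values measure the spread between these libraries, which may be technical. Counts of the same fraction at different doses differed far beyond sampling noise (chi-square per degree of freedom 32.9 to 90.3). No library was therefore taken for a technical repeat of another. In the contrasts of dox within a fraction and of line, however, the doses stood as the replicates of the dox arm. The spread in these contrasts came from the differences between doses, so it includes any effect of dose. The labels give both fractions of each line and dose, and the culture was therefore used as a block. As a check, the deviations of both fractions of a culture from their fraction means were correlated across genes. The correlation was 0.37 for H1 and between −0.00 and 0.07 for the 4 iETS1 cultures. The pairing is thus an assumption that the data do not bear out for iETS1. For H1, which is another line, a shared culture and the line cannot be told apart.

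Differential expression was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, on genes with at least 1 CPM in at least 2 libraries, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fraction was tested over 10 libraries with the culture as a block, and its dependence on dox as an interaction in that design. Dox within a fraction and line without dox were contrasts in a fit of 1 mean per fraction and arm, so that lone control libraries were taken to vary like the dox arm. Dose was tested as a slope over the 6 treated libraries with the fraction as covariate. Day 4 has 1 library per arm and was not tested: log2 ratios used CPM plus 1, and ratios of counts carry exact (Clopper-Pearson) 95% intervals. Per-library levels of ETS1 and DLL4 on both days are CPM of the library total where given for each library, and all other CPM are TMM-normalized. Where a group had 0 counts, a bound was computed against 3 counts over that group. Intervals and bounds cover counting error only.

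Before the data were examined, 30 gene lists were fixed for endothelial subtypes, Notch and ETS1 biology, blood, contaminating cell types, cell cycle and stress. Lists with at least 5 tested members entered camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, with an estimated correlation as alternative; 3 lists had too few, HOXA with 3 tested genes, early mesoderm with 4 and mitochondrially encoded mRNAs with 0 in the table. On day 4 a list's median was ranked among 10000 random lists matched on expression, for the 21 lists measured. Named genes followed a rule fixed at the same time, with ETS1 and DLL4 always named. Added were the 10 largest rises and the 10 largest falls among genes past the threshold with at least 10 mean CPM. These also needed the same direction in every culture for the fraction, and at every dose for dox within a fraction. The interaction, dose and line had no condition on direction. Up to 4 members of each list with the smallest p were named too (on day 4, the largest absolute log2 ratio at 10 CPM or more). Values of other genes named in the closing part were chosen after they were seen. Gene positions come from the GENCODE annotation mapped to GRCh37, the same assembly as hg19, where 361 of 377 named symbols matched 1 gene.

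The fits were tested on simulated data with 1 mean per gene over all libraries of the fit, the real dispersions and library sizes, and 200 changed genes. Simulated libraries were independent and otherwise held no differences between fractions, lines or cultures. The low number of genes detected in the DLL4+ iETS1 library without dox was not simulated either. The shares below do not cover these sources of error. With log2 changes of 1 and 2, edgeR recovered 22.9% and 61.1% in the fraction design (13405 genes run), 2.04% and 53.2% for dox in DLL4+ cells (13386), 7.37% and 51.0% for dox in DLL4− cells (13417), 5.26% and 40.0% for the interaction (13380), 16.3% and 57.4% for the dose slope (12686) and 7.14% and 50.5% for the line (13415). False calls made up 4.76%, 16.1%, 9.38%, 21.8%, 9.09% and 5.00% of the calls in these designs. Alternatives were DESeq2 1.42.0, relative log expression factors, no filter on low counts, limma on log2(TPM + 1), leaving out each culture or dose, other subsets and other control arms. Tests on the library labelled DLL4+ iETS1 without dox were added after its number of detected genes was seen.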

Results

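The study followed human embryonic stem cells as they became endothelium and blood-forming endothelium, and asked what raising the transcription factor ETS1 does to arterial identity. H1 is an established human embryonic stem cell line. Its derivative, here called iETS1, carries an ETS1 transgene that doxycycline (dox), an antibiotic used as a genetic switch, turns on together with a green fluorescent protein. RNA was sequenced in 12 libraries. The 2 day 4 libraries came from cells sorted for VE-cadherin, an endothelial adhesion protein, from iETS1 cultures without dox or with dox from day 2. The 10 day 5 libraries came from hemogenic endothelium sorted into DLL4+ and DLL4− fractions, DLL4 being a Notch ligand of arterial endothelium. Each fraction was taken from 5 cultures, as defined by line and dose: H1, iETS1 without dox, and iETS1 with dox at 1, 1.5 and 2 µg/ml. Each condition had 1 library, so the 3 doses stood as the 3 libraries of the dox arm. Total counts per library ranged from 6977993 to 15739131 on day 5 and were 3931671 (no dox) and 2735748 (dox) on day 4.

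ETS1 (chromosome 11, 128328656 to 128457453, GRCh37) checks the labels. On day 4 it stood at 911 CPM (counts scaled to the library total) without dox and 2991 with dox. On day 5 it was not higher in the libraries labelled dox. In the DLL4− fraction it measured 722, 724 and 484 CPM at 1, 1.5 and 2 µg/ml, against 780 in iETS1 without dox and 2290 in H1. In the DLL4+ fraction the same cultures gave 2423, 2324 and 2669 CPM, against 2707 and 2992. Every day 5 comparison of dox below therefore follows the labels, and ETS1 itself does not bear out its direction. DLL4 (chromosome 15, 41221538 to 41231271, GRCh37), the sort marker, lay between 4.20 and 16.9 CPM in the DLL4− fraction. In the DLL4+ fraction it was 654 CPM in H1, 186 in iETS1 without dox, and 396, 539 and 678 with rising dose.

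**Figure D1:**
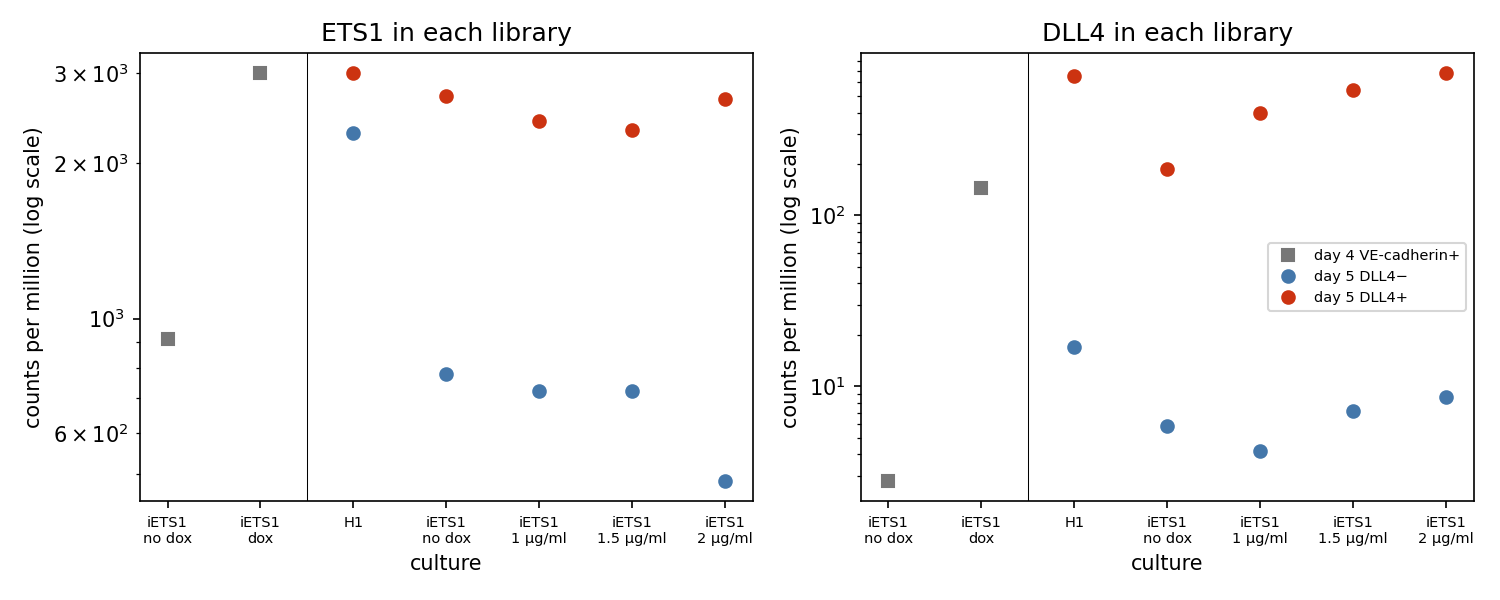
ETS1 (left) and DLL4 (right) in CPM in each of the 12 libraries, on log axes. Each point is 1 library: day 4 VE-cadherin+ cells as grey squares, day 5 DLL4− cells as blue circles and DLL4+ cells as red circles; ETS1 is 911 without and 2991 with dox on day 4, and on day 5 the H1 DLL4− library, at 2290, lies above the other 4 of its fraction.

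The library labelled DLL4+ iETS1 without dox held the fewest detected genes of the 10. It had 9587941 counts and 11771 genes with at least 1 count. Thinned to the 6977993 counts of the shallowest day 5 library, it kept 11565 genes, while the other 9 kept between 12896 and 15619. Of 6848 genes with at least 10 CPM in each of the other 9 libraries, 21 had 3 counts or fewer in it, and the corresponding number was 0 for every other day 5 library. Within the 5 DLL4+ libraries its gap to the nearest in genes kept was 0.375 of the range, under Dixon's critical value of 0.71. It is the only DLL4+ control of the iETS1 line, so its values enter both the dox and the line comparisons.

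**Figure D2:**
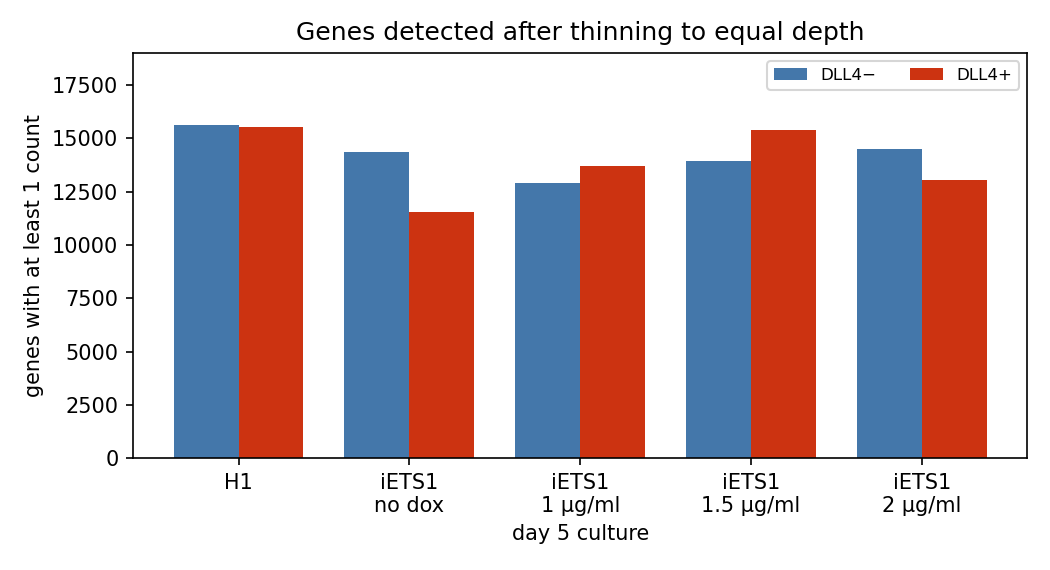
Genes with at least 1 count in each day 5 library after thinning to 6977993 counts, the depth of the shallowest library; bars are means of 5 draws, blue for DLL4− and red for DLL4+. The DLL4+ iETS1 library without dox has the lowest bar, 11565 genes, and the DLL4− H1 library the highest, 15619.

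On day 4, the arterial and endothelial program stood higher in the dox library. The library without dox held 13197 genes with at least 1 count from 3931671 counts, the dox library 15151 from 2735748. The library without dox thus held fewer genes despite more counts, and whether this raised the ratios below was not tested. ESM1, a tip cell proteoglycan, measured 2.01 CPM without dox and 1317 with dox, a ratio of 657 (95% interval 333 to 1522). CD93, a receptor of endothelium and stem cells, went from 6.27 to 910 CPM, a ratio of 145 (98.1 to 225). ROBO4, an endothelial guidance receptor, had 0 counts without dox and 161 CPM with dox, at least 214-fold higher against a floor of 3 counts, and the basement membrane collagen COL15A1 was at least 150-fold higher; the exact 95% intervals reach down to 174 and 121. DLL4 went from 2.76 to 146 CPM, a ratio of 52.9 (29.3 to 107), and ETS1 from 898 to 3033 CPM, a ratio of 3.38 (3.25 to 3.51). EMP1 and GAP43, and OIT3, TSPAN15, MYOZ2 and CBLN1 with 0 counts without dox, complete the 10 genes with the largest ratios. Those with the lowest were SLCO5A1 (at least 14.9-fold lower, with an exact limit of 11.8), CRB2, SNORD10, SPA17, SPTB, TEC, MYL4, BEX1, GLUD2 and MYOCD; BEX1 went from 1099 to 103 CPM, and MYOCD, a coactivator of smooth and cardiac muscle genes, from 78.8 to 7.04 CPM.

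Among the fixed gene lists, of 18 measured arterial genes, 15 were at least 2-fold higher with dox and 0 at least 2-fold lower, with a median log2 ratio of 3.08. Of 23 pan-endothelial genes 16 were higher, of 13 angiogenesis genes 9, of 18 Notch genes 9 and of 14 genes linked to ETS1 9, with medians of 2.03, 2.85, 1.11 and 1.42, and 1 angiogenesis gene was at least 2-fold lower. Of 12 interferon response genes 10 were higher and 1 lower, with a median of 3.54, among them IFIT1 (9.28 to 236 CPM) and OAS3 (at least 28.6-fold higher, with an exact limit of 22.5). Each of these 6 medians lay at the 100th percentile of 10000 random lists of equal size and matched expression. Mesenchymal genes lay at percentile 0 with a median of −1.48, 5 of 10 being at least 2-fold lower and 1 at least 2-fold higher; COL3A1 (94.1 to 10.7 CPM) and PDGFRB (26.3 to 4.82 CPM) were among the 5. Stress response genes had a median of −0.89 (percentile 0.02), 5 of 12 being at least 2-fold lower and 2 at least 2-fold higher. G1/S genes had a median of −0.67 (percentile 0.03) with 0 of the 19 past 2-fold. The ETS family had a median of 0.74 (percentile 99.98), 5 of 17 being at least 2-fold higher. For early response genes it was 0.56 (percentile 98.1). Pluripotency, G2 and M, HOXB and TGF-beta genes had medians of −0.72, −0.40, −0.67 and −0.50 (percentiles 0.665, 1.08, 1.24 and 1.78). Blood transcription factors went both ways, 1 of 10 at least 2-fold higher and 3 at least 2-fold lower (median −0.20, percentile 18.0), with GATA2 at 166 and 26.7 CPM and GFI1 at 273 and 55.6 CPM without and with dox. Over all 9458 genes with at least 10 CPM in 1 of the libraries, 1274 were at least 2-fold higher and 785 at least 2-fold lower, and 4399 differed 2-fold when 1 CPM was enough. With 1 library per arm these ratios compare libraries, not conditions, and the intervals cover counting error only.

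On day 5, the arterial genes EFNB2, HEY1 and NOTCH4 were higher in DLL4+ than in DLL4− cells in all 5 cultures. So was DLL4, the sort marker, whose difference the sort itself largely sets. DLL4 was 488 ± 194 CPM in the DLL4+ libraries and 8.31 ± 4.30 in the DLL4− libraries (mean ± SD, n = 5 each), a log2 difference of 5.88 ± 0.27 (SE; edgeR adjusted p = 5.19e-06). EFNB2, the arterial ephrin ligand (chromosome 13, 107142093 to 107188010), was higher by 3.51 ± 0.15, HEY1, a Notch target (chromosome 8, 80674606 to 80680092), by 3.95 ± 0.21, and the endothelial receptor NOTCH4 by 3.51 ± 0.22. ETS1 was also higher in DLL4+ cells, 2647 ± 284 against 971 ± 645 CPM (log2 1.65 ± 0.28, edgeR adjusted p = 0.00637). The largest rises were CLEC1B (6.96 ± 0.54), OIT3 (6.94 ± 0.48), COL15A1 (6.78 ± 0.82), ESM1 (6.68 ± 0.84), HPGD, the lipoprotein lipase LPL (6.04 ± 0.66), DLL4 itself, KL, the laminin chain LAMA4 (5.70 ± 0.66) and IGFBP3. The largest falls were TPPP3 (−5.46 ± 1.12), FREM2 (−4.02 ± 0.57), ROR2, KCNH2, the hyaluronan synthase HAS2 (−3.63 ± 0.68), NKD1, EMX1, UNC5C, the matrix protein TNC and PPFIBP2.

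Among the gene lists, 16 of 24 arterial genes rose in DLL4+ cells, 0 fell and 8 did not pass (18 rose when adjusted over the list alone). The list's median log2 difference was 1.99 (camera adjusted p = 2.37e-15). Of 25 pan-endothelial genes 17 rose and 0 fell (21 and 0 adjusted over the list alone; median 1.26, camera adjusted p = 1.22e-12), with PLVAP at 2.11 ± 0.20, ROBO4 at 4.42 ± 0.53 and CDH5, which encodes VE-cadherin, at 1.38 ± 0.18. Angiogenesis genes rose in 11 of 14 and Notch genes in 10 of 26 (11 up with 1 down, and 11 up with 2 down, adjusted over the list alone; camera adjusted p = 5.52e-07 and 0.000193). DLL4 itself belongs to the arterial, Notch and angiogenesis lists and was the sort marker. Genes linked to ETS1 rose in 12 of 20 and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 5.52e-07), NRP1 rising by 1.95 ± 0.20. G1/S genes fell in 12 of 19 (14 adjusted over the list alone; median −0.78, camera adjusted p = 1.59e-08), including the replication genes MCM4 (125 ± 26.6 against 254 ± 62.0 CPM) and TYMS. G2 and M genes fell in 3 of 20 (10 adjusted over the list alone; camera adjusted p = 0.00066). With an estimated correlation these calls were lost, at adjusted p = 0.227 for the arterial and G1/S lists, 0.253 for the pan-endothelial, 0.246 for the angiogenesis and ETS1-linked, 0.389 for the Notch and 0.484 for the G2 and M list.

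Blood transcription factors split. MECOM rose by 4.13 ± 0.33, while GFI1 (−1.66 ± 0.23), GATA2 (−1.54 ± 0.22) and RUNX1 (−1.47 ± 0.28) were among 5 of 18 that fell (2 up and 6 down adjusted over the list alone; camera adjusted p = 0.0687). Red cell and megakaryocyte genes fell in 2 of 10, mesenchymal genes in 3 of 14 and heart muscle genes in 1 of 11 (2, 6 and 1 adjusted over the list alone), with COL1A1 at 293 ± 236 against 820 ± 316 CPM and the heart and embryonic muscle gene MYL4 at −3.66 ± 0.88. Their camera adjusted p were 0.0396, 0.00926 and 0.00631, and adjusted p = 0.389, 0.484 and 0.484 with an estimated correlation. Interferon genes rose in 4 of 16 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00926, and adjusted p = 0.484 with an estimated correlation), with IFIT3 higher by 1.70 ± 0.38 in 4 of 5 cultures and IFITM1 lower by log2 −1.18 ± 0.20. The other lists did not pass as lists. Members higher and lower numbered 2 and 1 of 11 venous, 0 and 0 of 15 leukocyte, 0 and 0 of 6 lymphoid, 2 and 0 of 8 HOXB, 5 and 0 of 21 ETS family, 1 and 1 of 15 ERK feedback, and 1 and 2 of 15 TGF-beta genes. They numbered 0 and 3 of 11 pluripotency, 2 and 1 of 9 endoderm, 2 and 0 of 16 cell cycle inhibitor, 1 and 0 of 13 hypoxia, 2 and 1 of 18 early response, 1 and 2 of 16 stress, 2 and 0 of 16 sterol and 0 and 0 of 6 histone genes. Adjusted over the list alone these counts became 5 and 2 for venous, 3 and 0 for HOXB, 6 and 1 for ETS family, 2 and 1 for ERK feedback, 2 and 3 for TGF-beta, 3 and 4 for hypoxia, 2 and 4 for stress and 3 and 0 for sterol genes, and stayed the same for the other 7 lists.

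In total 1248 of 13939 genes differed between the fractions, 768 higher and 480 lower in DLL4+ cells, and 1190 of them had the same direction in all 5 cultures. The count was 2301 with DESeq2, 1899 in the dox-treated cultures alone, and 551, 441 and 586 without the culture at 1, 1.5 or 2 µg/ml. Without the iETS1 culture lacking dox, which holds the library with the fewest genes detected, it was 1654.

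Within the DLL4+ fraction, the Notch pathway genes DLL4, NOTCH4 and NRARP and 6 of 14 angiogenesis genes were higher in the 3 libraries labelled dox than in the library labelled iETS1 without dox. The Notch list as a whole was not among the 5 lists that passed in this contrast. With the DLL4+ H1 library as control, chosen after seeing the data, its median log2 difference was −0.19. DLL4 was 553 ± 159 CPM (mean ± SD, n = 3) against 205 in the control library (n = 1), a log2 difference of 1.43 ± 0.38 (edgeR adjusted p = 0.0447). NOTCH4 was higher by 1.67 ± 0.36, the Notch feedback gene NRARP by 2.84 ± 0.55, the chemokine receptor CXCR4 by 3.04 ± 0.80 and ESM1 by 2.79 ± 0.55. ETS1 differed by −0.23 ± 0.30 (edgeR adjusted p = 0.641). The 10 largest rises all had 0 counts in the control library: OAS3, WDR13, TNFRSF11A, IFIT5, NOP10, ADORA1, C4orf32, LOC100294145, RNPEPL1 and ANKRD6. Against a floor of 3 counts in that library they were higher by at least 7.93 (OAS3) to 5.63 (ANKRD6) on the log2 scale; NOP10, a component of a ribonucleoprotein that modifies RNA in most cells, is 1 of them. The largest falls were KLHL23, UNC13A, DLG3, CRABP2 (−3.08 ± 0.58), PPFIBP2, BEX1 (−2.47 ± 0.52), TIGD2, GPC3, CCDC69 and GCFC2.

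Of 24 arterial genes 4 rose in this contrast (11 adjusted over the list alone) and of 14 angiogenesis genes 6 (10 up and 1 down adjusted over the list alone), with median log2 differences of 1.12 (1.11 with genes at 0 in the control set to their bounds) and 1.71. Interferon genes rose in 3 of 16 (7 adjusted over the list alone), namely OAS3, OAS1 and IRF7, each at 0 in the control library. In the venous and pluripotency lists 1 gene each fell, FLRT2 (−1.53 ± 0.40) and DNMT3B (−1.22 ± 0.28), and 1 each adjusted over the list alone. All 5 lists had camera adjusted p = 0.0476, and adjusted p = 0.948 with an estimated correlation. Pan-endothelial genes rose in 2 of 25, ESAM (1.55 ± 0.29) and RASIP1 (1.59 ± 0.30), 3 adjusted over the list alone. Over all genes 979 differed, 891 higher and 88 lower, and 529 of the 891 had 3 counts or fewer in the control library, against which they were called. Restricted to genes with over 3 counts there, 193 passed, and with the DLL4+ H1 library as control in its place 14 (6 higher, 8 lower), with DLL4 at −0.06 ± 0.35. Against H1 the arterial and angiogenesis medians were −0.26 and −0.11 (camera adjusted p = 0.33 and 0.901), the venous and pluripotency medians −0.48 and −0.11 (0.143 and 0.901), and the interferon and G1/S medians 1.799 and 0.51 (2.06e-09 and 1.05e-05, and adjusted p = 0.392 and 0.692 with an estimated correlation). Both choices were made after seeing the data. With both untreated libraries as 1 arm edgeR called 0 genes (733 at an unadjusted p under 0.05), while in the design with the lone control DESeq2 called 1895, limma on TPM 649, edgeR on the 4 iETS1 libraries alone 1593, and the fits without 1 and 1.5 µg/ml 1595 and 103.

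Within the DLL4− fraction, 1 gene passed between the libraries labelled dox and the library labelled iETS1 without dox. PCSK6, a proprotein convertase (chromosome 15, 101829989 to 102065405), was 0.0800 ± 0.0114 CPM (n = 3) in the libraries labelled dox and 5.26 in iETS1 without dox. The log2 difference was −5.88 ± 0.56 (edgeR adjusted p = 0.00299). PCSK6 was lower at all 3 doses, each set against that same library. Its treated levels lie under 3 counts, which are 0.247, 0.245 and 0.207 CPM of the library total at 1, 1.5 and 2 µg/ml. Neither the SD nor the size of the log2 difference is therefore well determined. DLL4 (0.26 ± 0.40) and ETS1 (−0.19 ± 0.30) did not pass (edgeR adjusted p = 0.994 for both). The scavenger receptor gene STAB1 (−2.06 ± 0.35, edgeR adjusted p = 0.28), L1TD1 (3.22 ± 0.64, 0.458) and the growth factor PDGFB (−2.42 ± 0.51, 0.54) had the next smallest p among the list genes and did not pass. No member of the 18 blood transcription factors passed over all genes or adjusted over the list alone, but the list as a whole lay lower with a median of −0.73 (camera adjusted p = 0.000958). Red cell and megakaryocyte genes (median −0.81, camera adjusted p = 0.0199) and cell cycle inhibitors (−0.34, 0.0449), likewise with 0 members past either threshold, did too; with an estimated correlation the 3 lists had adjusted p = 0.6, 0.533 and 0.533. At an unadjusted p under 0.05 edgeR gave 802 of 13939 genes; DESeq2 called 49, edgeR without a filter on low counts 36, and limma on TPM and edgeR on the 4 iETS1 libraries alone 0 (814 and 584 at an unadjusted p under 0.05). Without the culture at 1 µg/ml edgeR called 72 genes, without 1.5 or 2 µg/ml 0 (443 and 796 at an unadjusted p under 0.05), and with the H1 library as control, chosen after seeing the data, 222 (35 higher, 187 lower), where ETS1 differed by −1.66. With that control the 3 lists no longer passed, at medians of −0.43, −0.01 and −0.20 (camera adjusted p = 0.064, 0.764 and 0.217). Other lists passed in their place, among them pan-endothelial (−1.15), ETS1-linked (−1.04) and arterial genes (−0.82) lower and G1/S genes (0.57) higher than in H1. They did not pass with an estimated correlation. In DLL4− cells iETS1 without dox already differed from H1 by −0.67, −0.83, −0.82 and 0.35 in the same order. Dox against iETS1 without dox, fitted without the DLL4+ library of that culture, gave −0.23, −0.23, 0.04 and 0.22. The contrast with H1 thus holds the difference between the lines as well as dox.

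By the interaction test, the difference between DLL4+ and DLL4− cells was not the same in treated and untreated cultures for 14 genes. In 10 of them the log2 difference, DLL4+ minus DLL4−, was higher in the 3 treated cultures than in the 2 untreated ones, iETS1 without dox and H1: PCSK6 (by log2 6.96 ± 0.94), PDGFB (5.20 ± 0.68), IGFBP3 (4.87 ± 0.70), COL15A1 (4.03 ± 0.46), LPL, GIMAP8, STAB1 (2.75 ± 0.41), TMEM173, which acts in the response to cytosolic DNA, the hypoxia factor EPAS1 (2.66 ± 0.36) and GPX1. In 4 it was lower: L1TD1 (−4.33 ± 0.57), TNC (−3.87 ± 0.54), the lymphocyte adhesion gene SELL (−2.65 ± 0.41) and TMEFF1 (−2.44 ± 0.37). TNC and SELL were already lower in DLL4+ cells in both untreated cultures and lay further below in treated ones (mean log2 differences −4.32 and −2.94), while L1TD1 and TMEFF1 went from above 0 to −2.77 and −1.28. For PCSK6 the DLL4− level carried the difference: 0.0680 to 0.0908 CPM in treated cultures, 5.26 in iETS1 without dox and 18.0 in H1. All 5 DLL4+ libraries lay between 21.5 and 27.7. The treated DLL4− levels of PCSK6 lie under 3 counts, so the size of its log2 value is not well determined. DLL4 (1.16 ± 0.29, edgeR adjusted p = 0.222) and ETS1 (0.81 ± 0.49, 0.751) did not pass. The 2 untreated cultures are H1, another line, and the iETS1 culture that holds the library with the fewest genes detected. The test therefore does not separate dox from differences between lines and libraries.

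**Figure D3:**
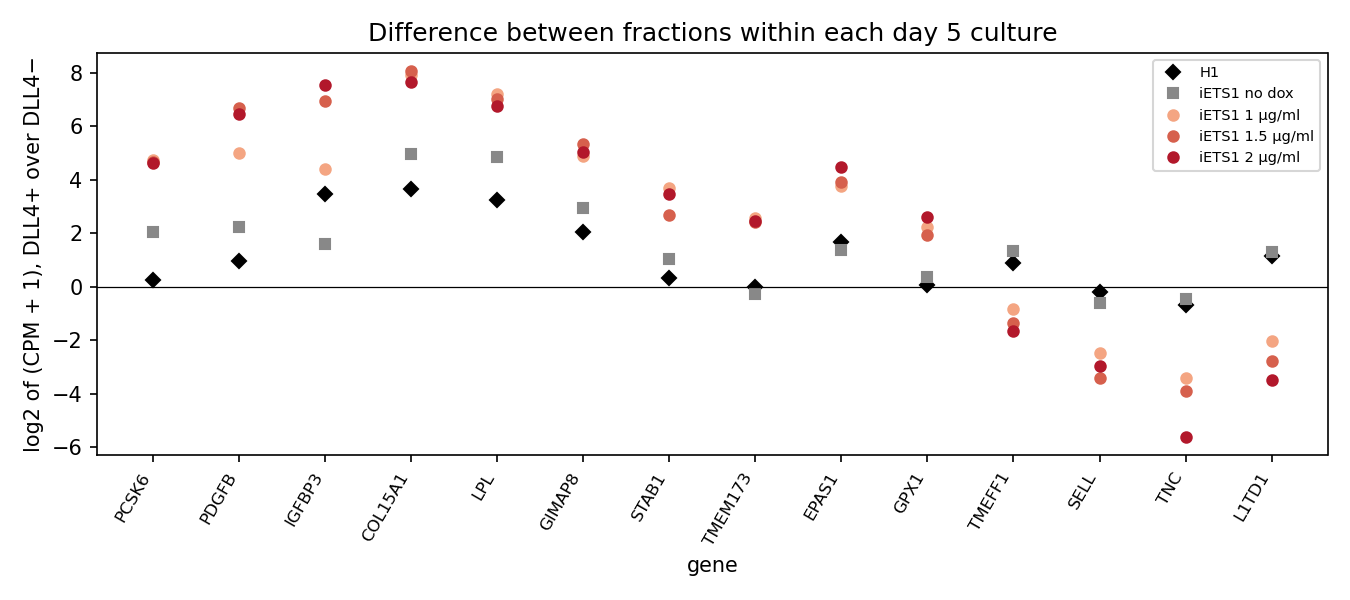
Log2 ratio of CPM + 1 between DLL4+ and DLL4− cells within each day 5 culture. Shown are the 14 genes whose fraction difference was not the same in treated and untreated cultures. Circles are the dox doses, the square is iETS1 without dox and the diamond is H1, 1 library pair each. For PCSK6 the 3 treated cultures average 4.66, against 2.03 without dox and 0.24 in H1; for TNC they average −4.32, against −0.48 and −0.68.

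Interferon genes as a list had a higher DLL4+ minus DLL4− difference in treated cultures, with a median of 2.12 over 16 genes (camera adjusted p = 0.00109). None passed over all genes and 10 were higher adjusted over the list alone. Pan-endothelial genes (median 0.76, 0 of 25 and 5 adjusted over the list alone, camera adjusted p = 0.00111) followed, as did arterial and Notch genes (0.75 and 0.69, 1 of 24 and 0 of 26, and 4 and 3 adjusted over the list alone, both 0.0435). Pluripotency genes had a lower difference with dox (median −1.42, 1 of 11 and 2 adjusted over the list alone, camera adjusted p = 0.00111). With an estimated correlation these 5 lists had adjusted p = 0.287. A further 6 lists passed (angiogenesis, ETS1-linked, leukocyte, TGF-beta and early response up, G2 and M down), with adjusted p between 0.287 and 0.52 with an estimated correlation. DESeq2 called 148 genes, edgeR without a filter on low counts 216 and limma on TPM 0, with 1273 at an unadjusted p under 0.05 against 1101 for edgeR. Without H1 edgeR called 574 genes, without iETS1 lacking dox, which includes the library with the fewest genes detected, 67, without 1 µg/ml 31, and without 1.5 or 2 µg/ml 0 (586 and 998 at an unadjusted p under 0.05).

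Among the treated cultures, 30 of 13220 genes had a slope over dose past the threshold, 16 up and 14 down. FGFBP3, a carrier of fibroblast growth factors (chromosome 10, 93666341 to 93669243), fell by 2.52 ± 0.23 on the log2 scale per µg/ml (edgeR adjusted p = 0.00308), from 432 to 192 to 62.5 CPM in DLL4− cells and from 82.0 to 42.4 to 17.2 in DLL4+ cells. The kinase BTK (−2.80 ± 0.33), PTGS1 (−2.36 ± 0.26), SAMSN1 (−1.97 ± 0.22) and the collagen COL1A1 (−1.56 ± 0.26) fell too, with SDPR, GMPR, TM4SF1, IGFBP5 and DANCR. The largest rises were CPE, ADM, IGFBP3 (3.20 ± 0.50), CLDN11 (2.67 ± 0.37), FREM2 (2.65 ± 0.35), FGF12, PEG10, TUBB2A, PCSK2 and RBP1. DLL4 had a slope of 0.84 ± 0.21 (edgeR adjusted p = 0.18), EFNB2 of 1.01 ± 0.20 (0.0886) and ETS1 of −0.25 ± 0.24 (0.817), and none of the 3 passed.

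In the arterial list 1 of 23 genes, IGFBP3, rose with dose and 11 rose adjusted over the list alone (median slope 0.57, camera adjusted p = 0.00121). Blood transcription factors had a median slope of −0.67 with 0 of 16 past the threshold, and 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.00337). Leukocyte genes fell in 1 of 12, CD44 (−1.37 ± 0.20), and in 3 adjusted over the list alone (camera adjusted p = 0.0109). Notch, endoderm, G1/S and G2 and M genes passed as lists with medians of 0.53, 1.36, −0.26 and −0.27, with 0 members past over all genes and 1, 2, 0 and 0 adjusted over the list alone. With an estimated correlation the 7 lists had adjusted p between 0.575 and 0.783. Both fractions of a culture entered the 6-library fit, so its p-values may be too small. Each dose had 1 culture, so a trend with dose cannot be told from differences between cultures. DESeq2 called 260 genes, limma on TPM 0 (1304 at an unadjusted p under 0.05, against 1279 for edgeR) and edgeR without a filter on low counts 351. The fit that adds no dox as dose 0 called 84. Without 1, 1.5 or 2 µg/ml 10, 40 and 64 genes passed, of which 2, 25 and 9 were among the 30.

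Without dox, the iETS1 libraries had lower levels of several arterial and endothelial genes than H1; 1 of the 2 iETS1 libraries here is the one with the fewest genes detected. Each line had 1 library per fraction, so the SDs hold the difference between fractions. The p-values do not measure the spread between cultures of a line and may be too small. NOTCH4 was 12.2 ± 13.2 CPM in iETS1 and 106 ± 126 in H1 (mean ± SD over the DLL4− and DLL4+ libraries, n = 2 each), a log2 difference of −2.88 ± 0.31 (edgeR adjusted p = 0.00206). EFNB2 (−1.95 ± 0.36), ESM1 (−2.97 ± 0.43), DLL4 (−1.47 ± 0.32) and the progenitor and endothelial surface gene CD34 (−1.32 ± 0.26) were lower, and ETS1 differed by −0.64 ± 0.26 (edgeR adjusted p = 0.162). The largest rises in iETS1 included C9orf64 (63.7 ± 36.8 against 2.25 ± 0.198 CPM, log2 4.69 ± 0.39) and PCDHGA11 (94.8 ± 13.8 against 6.08 ± 0.890 CPM), a protocadherin that shares exons with its cluster neighbours, so that its reads may be divided among them. Among the others named, PCSK2, TCEAL5, HAND1, CRHBP (3.21 ± 0.42), PPFIBP2, BEX1 (2.64 ± 0.53) and TMEM132C were higher, and 1 further gene of the 10 is not named here. The 10 genes with the largest deficit in iETS1 were HERC2P2, LOC146880, DENND3, TNFRSF11A, NEURL4, SRGAP1, TENC1, ZNF606, SPSB3 and WDR13. All 10 were at 0 CPM in the DLL4+ iETS1 library, while in the DLL4− fraction WDR13 stood at 39.7 CPM in iETS1 and 40.5 in H1.

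Of 24 arterial genes 6 were lower and 1 higher in iETS1 (13 and 1 adjusted over the list alone), with a median difference of −1.29. Lower were also 8 of 25 pan-endothelial, 7 of 14 angiogenesis, 4 of 26 Notch and 3 of 20 ETS1-linked genes (13, 9, 7 and 4 adjusted over the list alone). Mesenchymal genes were higher in 4 of 14 (6 adjusted over the list alone), with COL3A1 at 197 ± 3.13 against 64.1 ± 3.37 CPM. G1/S and G2 and M genes were higher in 1 of 19 and 1 of 20, CCNE1 (1.74 ± 0.43) and PLK1 (1.02 ± 0.23), and in 1 and 6 adjusted over the list alone, with median differences of 0.52 and 0.50. Camera adjusted p lay between 0.000161 and 0.0297 for these and for the pluripotency and heart muscle lists, both with 0 members past and with 0 and 1 adjusted over the list alone, and adjusted p between 0.518 and 0.578 with an estimated correlation. In all 828 genes differed, 184 higher and 644 lower in iETS1. A fit in DLL4− cells alone and without the DLL4+ iETS1 library, chosen after seeing the data, sets 1 library against 1 and borrows the spread from the dox libraries. In it 6 genes passed (2 higher, 4 lower) and the arterial list had a median of −0.82 (camera adjusted p = 0.0013, and adjusted p = 0.562 with an estimated correlation). C9orf64 differed by 4.15 ± 0.56, PCDHGA11 by 3.96 ± 0.44 and NOTCH4 by −2.57 ± 0.44 (edgeR adjusted p = 0.103). DESeq2 called 1740 genes, edgeR without a filter on low counts 1313, limma on TPM 304, and the fits without the 1 or 1.5 µg/ml culture, which lend only their spread, 1583 and 37.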

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

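The tests on the library labelled DLL4+ iETS1 without dox, on ETS1 and on the 16 splits were chosen only after the results were seen. The test on pan-endothelial genes and the 100 splits of the samples were set before.

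ETS1 stood at 2290 CPM in the DLL4− H1 library, far from the other 4 libraries of that fraction: its gap to the nearest made up 0.836 of the whole range, above Dixon's critical value of 0.71. Of 10 such groups tested this was the only 1 past, and chance gives about 1 in 20 groups.

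The log2 difference between the fractions, DLL4+ minus DLL4−, was not the same in treated and untreated cultures, by the interaction test, for 14 genes. It was higher with dox for PCSK6 (log2 6.96, with under 3 counts in each treated DLL4− library), PDGFB (5.20), IGFBP3 (4.87), COL15A1 (4.03), LPL (3.13), GIMAP8 (3.02), STAB1 (2.75), TMEM173 (2.74), EPAS1 (2.66) and GPX1 (2.04). It was lower with dox for TMEFF1 (−2.44), SELL (−2.65), TNC (−3.87) and L1TD1 (−4.33); SELL and TNC were lower in DLL4+ cells with and without dox. It also differed for 11 gene lists by camera with a preset correlation, and for 0 with an estimated one (adjusted p = 0.287 or more).

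In the DLL4+ fraction 891 genes were higher in the libraries labelled dox. Depth of the lone control is argued against, since at equal depth it still held 11565 genes against 12896 to 15619 in the other 9 libraries. Low complexity of the control stays open: 21 genes with at least 10 CPM in each of the other 9 libraries had 3 counts or fewer in it, against 0 in any other library. All 21 are among the 891, which their choice by low counts in the control largely fixed. They are also too few to decide for the rest. A change by dox stays open as well: 5.05% of the 891 (45 genes) were at least 2-fold higher than in the DLL4+ H1 library, and their median log2 difference was −0.03 for dox over H1 and 2.77 for H1 over the lone control. The control thus lay below both, but the 891 genes were called for being low in it, so the 2.77 follows in part from that choice. H1 is another line and the control is 1 library, so low complexity of the control and a change by dox cannot be told apart.

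ETS1 was not higher with dox on day 5. An exchange of a treated with an untreated library stays open. Among the 4 iETS1 libraries the highest ETS1 was 1.61 times the lowest in the DLL4− fraction and 1.17 times in the DLL4+ fraction. An exchange would show in this spread only if dox still raised ETS1 on day 5, so the spread cannot decide. Whether the transgene's reads are counted under ETS1 stays open: on day 4 its log2 ratio was 1.75 (1.70 to 1.81), but of 315 other genes within 2-fold of its level without dox 1, the endothelial gene PLVAP, rose as much (2.21), so the cell's own ETS1 gene could also have risen. Loss of the induction by day 5 was not tested, and neither was dox itself, because H1 with dox is not among the libraries.

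Pan-endothelial genes were higher in DLL4+ cells, which non-endothelial cells diluting the DLL4− fraction could produce. An even dilution by cells that lack all these transcripts is argued against. Of 25 genes 14 lay more than 2 SE from the list's median of 1.26, 7 above and 7 below. A mixture with cells that express some of these genes and a difference in endothelial state stay open.

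Of 100 splits of the 10 libraries into 5 and 5, 1 gave as many as 1248 genes, the split by fraction itself, and the highest other gave 377. Because the culture is a block in the fit, the splits to compare are the 16 that part the libraries of every culture. Among the 15 others of these the highest count was 0, and 16 splits are too few for a share under 0.05.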

How the results depend on the processing

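The H1 controls, the fits without the library labelled DLL4+ iETS1 without dox and the restriction to genes above 3 counts in it were chosen after seeing the data; the other alternatives were planned. Gene counts stayed within 1.5 times with relative log expression factors in all 7 comparisons. For the fractions 1248 genes became 2301 with DESeq2, 1899 in treated cultures alone and 441 to 1654 leaving out 1 culture. Without the replicate block 1102 passed, 956 of them shared. For dox in DLL4+ cells 979 became 1895 with DESeq2, 649 with limma on TPM, 0 with both untreated cultures as 1 arm (edgeR, 733 at an unadjusted p under 0.05), 1593 in the 4 iETS1 libraries, 193 in genes above 3 counts in the control, 14 with the H1 control (1 shared) and 103 to 1595 leaving out 1 dose. With the H1 control these log2 differences changed sign: DLL4 −0.0575, WDR13 −0.12, TNFRSF11A −0.28, ADORA1 −0.41, C4orf32 −0.18, RNPEPL1 −0.42, ANKRD6 −0.47, PPFIBP2 1.76, BEX1 1.15 and CCDC69 0.26. For dox in DLL4− cells 1 became 49 with DESeq2, 36 without a filter, 0 with limma on TPM, 0 in the 4 iETS1 libraries, 222 with the H1 control and 0 to 72 leaving out 1 dose (0 with 443 and 796 at an unadjusted p under 0.05); DLL4 turned to −0.61 with both untreated cultures as 1 arm and −1.19 with the H1 control. For the dependence of the fraction difference on dox 14 became 148 with DESeq2, 216 without a filter, 0 with limma on TPM, 574 in iETS1 cultures alone, which leaves out H1, and 0 to 574 leaving out 1 culture; ETS1 ranged from −0.0156 to 1.62 across the left-out cultures and was −0.0156 in iETS1 alone. For dose 30 became 260 with DESeq2, 351 without a filter, 0 with limma on TPM, 84 with no dox as dose 0 and 10 to 64 leaving out 1 dose. For the line 828 became 1740 with DESeq2, 1313 without a filter, 304 with limma on TPM, 37 to 1583 leaving out 1 dose and 6 in DLL4− cells alone. On day 4 2059 of 9458 genes became 4399 of 13921 with genes from 1 CPM on. Of 162 list tests 47 passed with the preset correlation and 0 with an estimated one. With limma on log2(TPM + 1), which changes both the measure and the fit, the median of all genes went from 0.01 to 0.11 for dose and from −0.18 to −0.41 for the line. Where a cause is not named it was not tested. Among named genes 228 of the alternative values kept their side of the threshold and 24 lost it for the fractions, against 149 and 73 for dox in DLL4+ cells, 112 and 45 for the dependence on dox, 113 and 61 for dose and 137 and 39 for the line. Day 4 depth, 2735748 and 3931671 counts, limits ratios of genes at 0 to lower bounds. The day 4 library without dox also held fewer genes than the dox library (13197 against 15151) despite more counts.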

Other observations

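The comparison of day 4 rises with the day 5 fractions was chosen only after the result was seen; that with dox in DLL4+ cells was set before. Genes named here were chosen after their values were seen.

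The genes C9orf64 and PCDHGA11 separated the lines in every day 5 library, and how many others did so was not counted. C9orf64 lay between 37.7 and 89.7 CPM in all 8 iETS1 libraries, with or without dox and in both fractions, and at 2.39 CPM or less in both H1 libraries. PCDHGA11 lay between 85.1 and 167 CPM in the iETS1 libraries and at 5.45 and 6.71 CPM in H1, with the reservation that protocadherin reads are shared within the cluster.

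Interferon genes were also higher as a list in the DLL4+ libraries labelled dox than in H1, a control chosen after seeing the data. The list's median log2 difference was 1.799, with 0 of 15 members past the threshold over all genes (camera adjusted p = 2.06e-09, and adjusted p = 0.392 with an estimated correlation). In DLL4− cells the median against H1 was −0.73 (camera adjusted p = 0.125). ISG15, an antiviral protein that is attached to other proteins, measured 2371, 1327 and 1815 CPM in DLL4+ cells at 1, 1.5 and 2 µg/ml, 1159 without dox and 388 in H1. In DLL4− cells it measured 526, 421 and 218 CPM at these doses, 625 without dox and 602 in H1. Its slope over dose was −0.78 ± 0.28 (edgeR adjusted p = 0.39). Whether dox, the transgene or the line carries this is not separable here.

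The 1274 genes at least 2-fold higher with dox on day 4 may form a program that on day 5 separates DLL4+ from DLL4− cells. Their median log2 difference between the day 5 fractions was 0.77, at percentile 100 of matched random lists (−0.09 to −0.02), and 460 of them were higher and 7 lower in DLL4+ cells. Whether the same genes rise with dox within DLL4+ cells on day 5 stays open, because the controls gave opposite answers. Their median lay at percentile 100 against iETS1 without dox (0.58) and at percentile 0 against H1 (−0.12). The test set before asked for a rise against both, but H1 also differs by line and the iETS1 control is the 1 library with the fewest genes detected, so neither control decides.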
